A study of Homo sapiens with 32 samples.

How the data were processed

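Gene expression was measured on Illumina BeadChips of 22184 probes in 32 samples of ECC-1, a human epithelial cell line that responds to steroid hormones. Per the labels, the line derives from the endometrium, while the series title speaks of endocervical cells, and the origin of the line was not settled here. The labels give 8 treatments: no hormone (Control), oestradiol (E), progesterone (P), both hormones (E+P), Chlamydia trachomatis serovar D without hormone (C), and infection with each hormone treatment (E+C, P+C and E+P+C). Hormones were given 24 h before infection and the doses are not stated beyond physiological averages. Each treatment has 1 array at 12 h and 3 arrays at 24 h. Nothing in the labels says that the 3 replicates came from separate cultures, so p-values may measure technical spread alone.

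The deposited scanner table holds intensity values on a linear scale, per the file headers a signal and a detection p for each probe and array. Although the table is called non-normalised, the quartiles were nearly the same on all arrays (46.4, 69.9 and 312 to 314), which shows that arrays had been quantile-normalised before deposit. No value was negative (lowest 30.7, highest 24004.8), so background had not been subtracted. The deposited detection p-value, per the file headers, is given per probe and array, and its steps imply 708 negative control beads. A deposited value table on the log2 scale carries no description of scale or centring. Set against the scanner table, it equalled log2 intensity minus each probe's median over the 32 arrays, with a largest difference of 0.00448, once probes of the same gene were exchanged for 4032 of the 6789 probes of genes with several probes. Which of the 2 tables pairs those identifiers with the right probe stays unknown. Column medians of the value table lay between -0.0187 and 0.0222.

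The design, fixed before the data were examined, named limma's neqc. Because the table was already quantile-normalised, background was instead corrected with limma's normexp (offset 50) without further normalisation, and log2 values were tested. Neqc with an offset of 16 became an added alternative. Changes of dim genes are understated on the log2 scale with this offset. A probe entered a fit if its detection p was under 0.01 on at least 3 arrays of that fit, which left 11851 probes at 24 h, 11336 at 12 h and 12789 in the fit of all 32 arrays. Detected probes per array numbered 10062 to 11559 at 12 h and 10128 to 11263 at 24 h. The number of arrays limits the precision.

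Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). The 24 arrays of 24 h shared a model with a mean for each of the 8 groups. The 8 arrays of 12 h were fitted with additive terms for oestradiol, progesterone and infection, each balanced 4 against 4, with interactions taken as residual spread. The change of the infection effect with time came from a joint fit of all 32 arrays. The labels give no hybridisation batch or chip, and time and batch cannot be told apart. For a gene detected on no array of a group, and for most named genes detected on only some of its arrays, the change is given as "at least N-fold", the other group's mean against, per array, the higher of the probe's own level and the lowest level detected on that array (6.38 to 6.65 at 24 h, 6.33 to 6.67 at 12 h). The fitted log2 change printed beside such a bound depends on the background and is not itself a bound.

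Gene names are those of the array table. Of its probes, 17779 carry a current RefSeq symbol (assembly GRCh38.p14, used for names alone), 3252 a unique older symbol and 1121 neither, and 32 symbols had turned into dates and were left unnamed. IL8 is now CXCL8, CTGF is CCN2, SGK is SGK1, ISGF3G is IRF9 and LRAP is ERAP2. Of 18102 gene names, 2834 have more than 1 probe, and a gene was represented by its probe of highest mean level at 24 h. Genes were named by a fixed rule: the 10 largest rises and falls per comparison among called genes whose groups do not overlap (no such condition for interactions and 12 h factors), the 5 smallest p where fewer than 5 pass, up to 4 called members of each described list (otherwise the 2 with the smallest p), and PGR, ESR1, FKBP5, GREB1, IL6, IL8 and TLR4. Among 29 further probes of called named genes at 24 h, 9 (in 8 genes: CD44, OAS2, OAS1, IFIT3, TPM2, PILRB, CDK5RAP3 and IFIT1) were not called and 0 had the opposite sign.

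Before the data were examined, 30 gene lists were fixed from general knowledge and tested with limma's camera (preset correlation 0.01, with an estimated correlation as the alternative). They covered interferon-stimulated genes, pattern-recognition receptors and adaptors, NF-kB regulators and feedback inhibitors, cytokines and chemokines of epithelial inflammation, inflammasome and pyroptosis, complement and coagulation regulators, antimicrobial proteins and mucins, and MHC and antigen presentation. Hormone and metabolism lists were oestrogen-responsive genes, progesterone- and glucocorticoid-responsive genes, steroid and xenobiotic metabolism, cholesterol synthesis and uptake, fatty acid and phospholipid synthesis, glycolysis and hypoxia response, oxidative phosphorylation subunits, iron homeostasis, and tryptophan and kynurenine metabolism. Stress and growth lists were unfolded protein and integrated stress response, heat shock response, oxidative stress and metal response, S and G2/M phase genes, replication-dependent histones, immediate early genes, apoptosis regulators, p53 targets and ribosomal proteins. Cell type lists were epithelial cell and junction markers, stromal and mesenchymal markers, leukocyte markers and endothelial markers. Single arrays at 12 h were compared by list medians, as percentiles among 10000 random lists of matched size and level.

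The fits were tested on simulated data. In P+C against C (11851 probes), 36 of 67 probes changed by 0.5 log2 units were recovered, 67 of 67 changed by 1 and 66 of 66 changed by 2, with 8 unchanged probes called. For infection at 12 h (11336 probes), 22 of 67, 60 of 67 and 66 of 66 were recovered, with 5 unchanged probes called. Without any change, 0 probes and 0 of 29 lists were called. With 1 list raised by 1 log2 unit, 2 lists were called, the raised list and another. Lists share members, so the other may hold raised genes. Probes were simulated independently, so these counts do not show how often lists are called falsely when genes correlate.

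The alternatives were no background correction, median scaling, the deposited value table, neqc, other filters on dim probes, a replicate block, a joint fit for the 12 h terms, an estimated correlation for lists, and leaving out each array. Chosen after the data were seen were normexp as the main correction and neqc, named in the design, as an alternative to it. Added then too were the fits without E replicates 1 and 3 or without P replicates 1 and 3, leaving out each array in the joint fit, and contrasts of progesterone in the presence of oestradiol. Figures were drawn with matplotlib 3.10.9.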

Results

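The series comprises 32 arrays of total RNA from ECC-1 cells, a hormone-responsive human epithelial line. Cells received oestradiol, progesterone, both or neither, and were left uninfected or infected with Chlamydia trachomatis serovar D, an obligate intracellular bacterium. There was 1 array for each of the 8 treatments at 12 h and 3 at 24 h, and the study asked how the female sex hormones act on the infected cell. Values are log2 intensities, changes are differences of log2 means ± the standard error of the fit, and n = 3 arrays per group at 24 h unless stated. Replicate arrays at 24 h correlated at 0.953 or higher across probes (median 0.994). The lowest value lay between E replicates 1 and 2. C replicate 3 also stood apart from the other C arrays, at 0.972 and 0.977, against 0.994 between those. Across times, arrays correlated at 0.785 to 0.879.

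**Figure D1:**
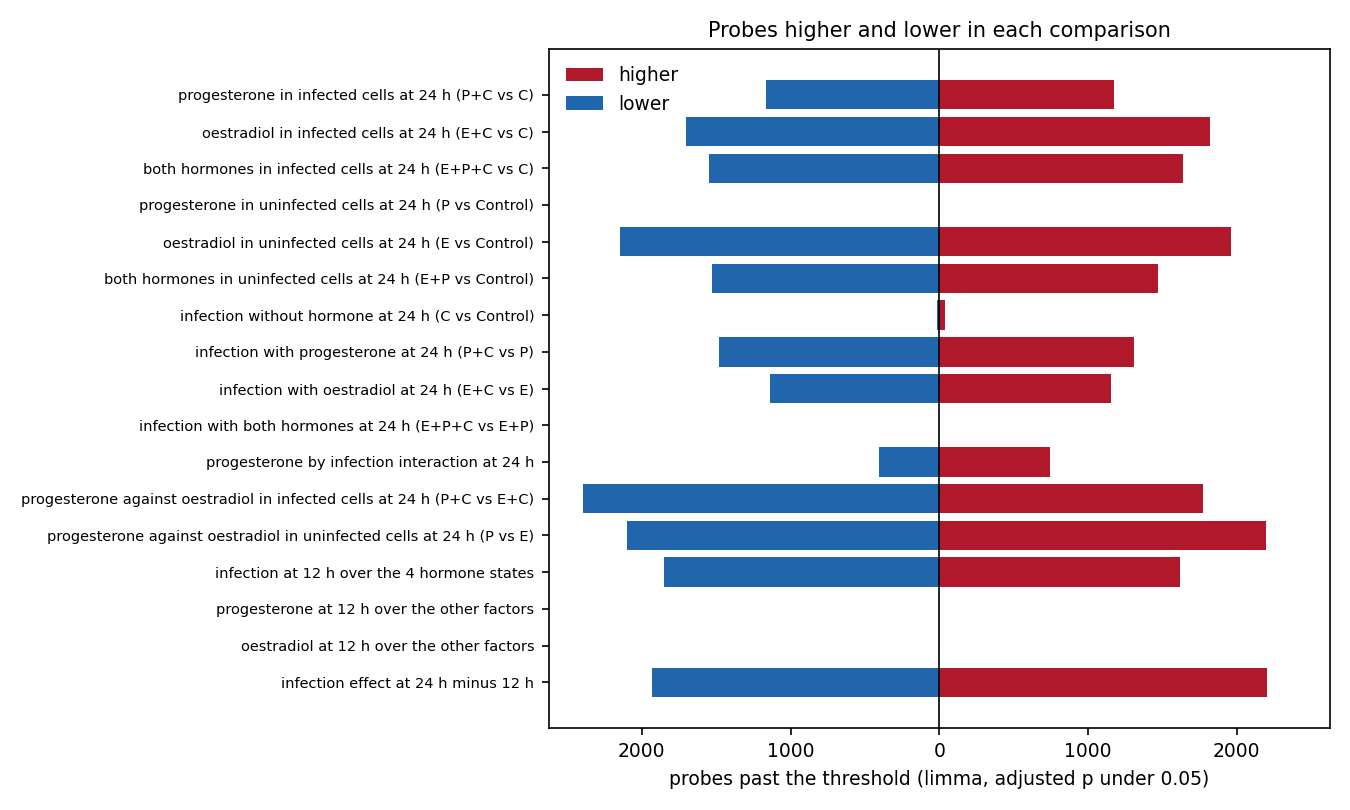
Number of probes higher (red, right) and lower (blue, left) in each comparison at an adjusted p under 0.05 (limma), with the comparisons on the vertical axis. Progesterone without infection changed 1 probe, while progesterone in infected cells changed 2343.

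Infection without hormone, the C group against Control at 24 h, raised interferon-stimulated genes. OAS2, an antiviral enzyme that senses double-stranded RNA, rose by 1.82 ± 0.293, and IFI44L rose at least 2.67-fold (1.52 ± 0.173). XAF1, an interferon-induced promoter of apoptosis, rose by 1.60 ± 0.202 and ISG15, a ubiquitin-like modifier, by 1.09 ± 0.191. IFIT1, which binds foreign RNA, rose by 1.74 ± 0.318, a call lost without Control replicate 2 (1.59). The largest falls were in TPM2, an actin-binding tropomyosin (-1.12 ± 0.113), FOS, an immediate early transcription factor (-0.91 ± 0.145), and CTGF, a matrix-associated growth factor (-0.74 ± 0.0877). IL6 and IL8 lay below background in both groups.

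Of 38 measured interferon-stimulated genes, 24 rose, 0 fell and 14 did not pass over all probes, and 32 rose when adjusted over the list alone (median 0.85, camera adjusted p = 1.71e-72, and adjusted p = 0.00066 with an estimated correlation). MHC and antigen presentation was the other list called (median 0.17, adjusted p = 0.000154, and adjusted p = 0.0102 with an estimated correlation). None of its 16 measured genes passed over all probes and 2 did when adjusted over the list alone, TAP2 at 0.68 ± 0.159 and TAP1 at 0.52 ± 0.121, and without C replicate 3 the list was not called. In all, limma called 56 of 11851 probes (38 rose, 18 fell), with 757 at an unadjusted p under 0.05. Another TPM2 probe (-0.75) and 1 of the 3 other OAS2 probes (0.83) were not called.

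Progesterone without infection, P against Control at 24 h, lowered CTGF by -0.68 ± 0.0877 (adjusted p = 0.000786, limma). This was 1 probe of 11851, with 504 at an unadjusted p under 0.05. The next smallest p belonged to genes that did not pass: EGR1, an immediate early transcription factor, at -0.65 ± 0.117, RGS16 at -0.52 ± 0.0972, and FOS at -0.75 ± 0.145. The same Control arrays were the reference for C against Control, where CTGF and FOS fell too, so the falls in these comparisons are not independent. FKBP5, a common progesterone and glucocorticoid target, stood at -0.10 ± 0.121. None of 38 interferon-stimulated genes rose, and 1 fell when adjusted over the list alone. Their median of 0.24 was called by camera (adjusted p = 2.01e-10), but with adjusted p = 0.436 with an estimated correlation. The count was 2 with no filter on dim probes and 3 among probes detected on every array. PGR, the progesterone receptor, was below background in both groups.

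Progesterone in infected cells, P+C against C at 24 h, is the comparison named in the series title, and inflammatory genes rose steeply in it. CCL20, a chemokine for dendritic cells and T cells, rose at least 83.8-fold (6.47 ± 0.135), to 12.96 ± 0.153 (SD), and was near background in C, where 2 of 3 arrays detected it. IL8, a neutrophil chemokine, rose by 5.88 ± 0.0999, at least 45.4-fold, CXCL10, an interferon-inducible chemokine, at least 34.8-fold (5.22 ± 0.111), and the monocyte chemokine CCL2 at least 15.3-fold (4.45 ± 0.128). The epithelial cytokine IL17C rose at least 28.7-fold (4.93 ± 0.106) and TNF by 4.02 ± 0.162. CX3CL1, a membrane-bound chemokine, rose at least 17.5-fold (4.68 ± 0.0838) and IL6 at least 10.1-fold (3.98 ± 0.123). S100A8, a subunit of the neutrophil protein calprotectin, rose by 4.08 ± 0.122.

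**Figure D2:**
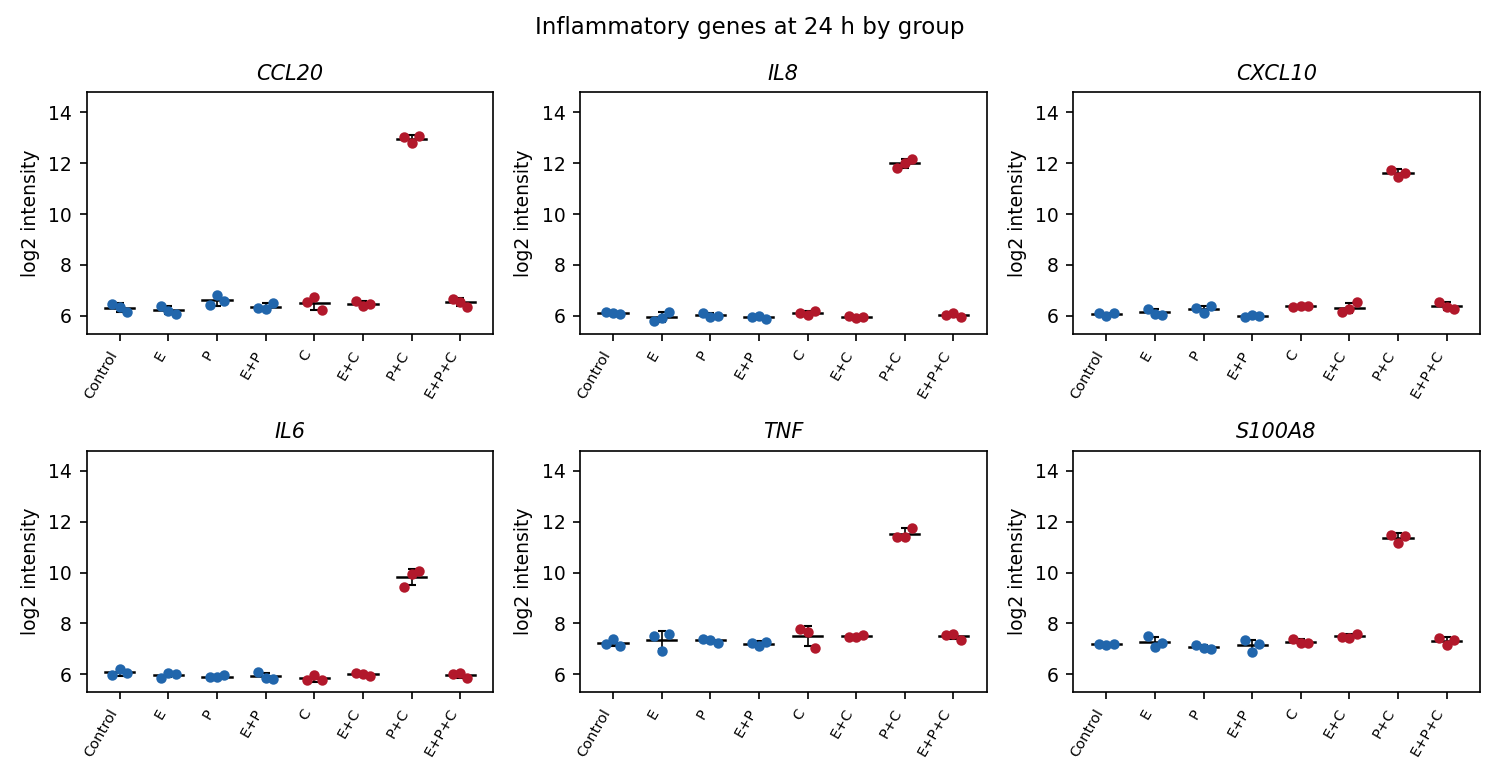
Log2 intensity of 6 inflammatory genes at 24 h in each group, with uninfected groups in blue, infected groups in red, a point for each of 3 arrays, a bar at the mean and an error bar of 1 SD. In P+C, CCL20 averaged 12.96 and IL8 11.99, against 6.49 and 6.11 in C.

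By list, 23 of 27 measured cytokines and chemokines of epithelial inflammation rose and 0 fell (median 2.08, adjusted p = 2.23e-45). The count was 23 when adjusted over the list alone. The list has 38 members on the array. The filter of 3 arrays can be met by the P+C arrays alone, so lists in P+C comparisons favour members that are high there. Among probes detected on every array this list was still called. Of 23 NF-kB regulators and feedback inhibitors, 18 rose (20 adjusted over the list alone). Among them were BIRC3, an inhibitor of apoptosis (3.69 ± 0.136), TNFAIP3, which ends NF-kB signalling (3.54 ± 0.13), and the kinase MAP3K8 (3.30 ± 0.125). Immediate early genes gave 16 rises and 2 falls among 26 (21 and 2 adjusted over the list alone), with IER3 at 3.09 ± 0.137 and MYC at 2.35 ± 0.22. Antimicrobial proteins and mucins rose in 5 of 9 (5 adjusted over the list alone). LCN2, which binds bacterial iron carriers, reached 3.44 ± 0.202, while S100A9, the partner of S100A8, rose at least 6.56-fold (2.92 ± 0.123) and the protease inhibitor PI3 at least 4.35-fold (2.66 ± 0.0859). In MHC and antigen presentation, 9 of 16 rose (11 adjusted over the list alone), including HLA-B (1.43 ± 0.162) and the peptide transporter TAP1 (1.42 ± 0.121).

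Interferon-stimulated genes gave 18 rises and 1 fall among 38 (19 and 1 adjusted over the list alone), led by the transcription factor IRF1 (2.75 ± 0.216), IFIT2 (2.58 ± 0.166), GBP1 (at least 2.53-fold, 1.97 ± 0.0893) and IFIT3 (1.95 ± 0.156). The list was called at adjusted p = 6.84e-12, but had adjusted p = 0.0748 with an estimated correlation. Pattern-recognition receptors and adaptors gave 9 rises and 1 fall among 23 (9 and 1 adjusted over the list alone), with IRAK2, a kinase below interleukin-1 and Toll-like receptors, at 3.42 ± 0.0901, and the NOD adaptor kinase RIPK2 at 1.87 ± 0.117. TLR4 was below background in both groups. In complement and coagulation regulators 8 of 18 rose (8 adjusted over the list alone). These included complement factor B (CFB, 3.18 ± 0.191) and the urokinase receptor PLAUR (at least 8.45-fold, 3.13 ± 0.131). Among probes detected on every array the complement list was not called. Apoptosis regulators gave 13 rises and 4 falls among 30 (14 and 4 adjusted over the list alone), with CFLAR, an inhibitor of caspase-8 activation, at 1.41 ± 0.126, and the death receptor TNFRSF10B at 1.35 ± 0.098.

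Progesterone- and glucocorticoid-responsive genes gave 12 rises and 5 falls among 29 (14 and 6 adjusted over the list alone). The leading members were CEBPD (2.69 ± 0.155), SGK (2.48 ± 0.11) and STAT5A (2.20 ± 0.119), which also respond to cytokines and stress, while FKBP5 was at 0.12 ± 0.121 and did not pass. Iron homeostasis rose in 6 of 12 (6 adjusted over the list alone), with the iron transporter SLC11A2 at 1.96 ± 0.101. Oxidative stress and metal response gave 8 rises and 2 falls among 27 (11 and 2 adjusted over the list alone), with the superoxide dismutase SOD2 at 2.89 ± 0.109 and the metallothionein MT1A at 1.81 ± 0.136. Tryptophan and kynurenine metabolism gave 4 rises and 1 fall among 11 (5 and 2 adjusted over the list alone), with KMO, an enzyme of kynurenine breakdown, up at least 3.09-fold (2.02 ± 0.0961), and the dioxin-inducible CYP1A1 at -0.91 ± 0.139. That list was no longer called when P+C replicate 1, 2 or 3 was left out. S and G2/M phase genes fell in 16 of 39 (22 adjusted over the list alone), with the replication helicase subunits MCM6 and MCM2 at -0.75 ± 0.122 and -0.56 ± 0.123.

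Inflammasome and pyroptosis genes rose in 3 of 8 (3 rose and 2 fell adjusted over the list alone), IL1B at least 1.94-fold (1.33 ± 0.103) and CASP4, a caspase that senses lipopolysaccharide, at least 1.52-fold (1.19 ± 0.105), with adjusted p = 0.104 with an estimated correlation. Unfolded protein and integrated stress response genes gave 8 rises and 3 falls among 30 (9 and 3 adjusted over the list alone). They had adjusted p = 0.195 with an estimated correlation, led by ATF3 (1.93 ± 0.109) and PPP1R15A (1.30 ± 0.102), both induced by stress. The 14 lists not called (adjusted p 0.101 to 0.987, medians -0.19 to 0.04) were p53 targets, leukocyte markers, fatty acid and phospholipid synthesis, oxidative phosphorylation subunits, heat shock response, steroid and xenobiotic metabolism, glycolysis and hypoxia response, cholesterol synthesis and uptake, replication-dependent histones, oestrogen-responsive genes, ribosomal proteins, endothelial markers, stromal and mesenchymal markers, and epithelial cell and junction markers. In the lists of p53 targets, glycolysis, cholesterol, oestrogen-responsive genes, ribosomal proteins and epithelial markers, the median was negative while the mean and the test pointed up. Leukocyte markers rose in 2 of 7 (median 0.04). The inflammasome list was not called without C replicate 3 or without any 1 of the P+C arrays, and the unfolded protein list not without C replicate 3 or P+C replicate 1.

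The largest falls were smaller than the rises. PSCA, a surface antigen of epithelia, fell at least 2.61-fold (-1.39 ± 0.164), the potassium channel gene KCNJ8 changed by -1.33 ± 0.127 and AFAP1L2, an adaptor of Src kinase, by -1.29 ± 0.106. In all, 2343 of 11851 probes passed (1176 rose, 1167 fell), of which 301 rose and 8 fell by at least 1 log2 unit, and without P+C replicate 3 the count was 1511. Falls outnumbered rises without C replicate 1 (1183 and 1159) or 3 (1192 and 1113) and among probes detected on every array (1017 and 826). The oestrogen receptor gene ESR1 changed by -0.30 ± 0.103 (adjusted p = 0.0396, limma), a call lost without any 1 of the P+C arrays, without C replicate 3 (-0.22) and with a replicate block.

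Infection in the presence of progesterone, P+C against P, gave the same leading chemokines, with CCL20 at 6.35 ± 0.135 (at least 79.3-fold), IL8 at 5.97 ± 0.0999 (at least 43.4-fold) and CXCL10 at 5.34 ± 0.111 (at least 33.2-fold). Interferon-stimulated genes rose in 32 of 38 (33 rose and 1 fell adjusted over the list alone, median 1.25, adjusted p = 4.28e-27, and adjusted p = 0.00707 with an estimated correlation), with IFIT2 at 3.36 ± 0.166 and IFIT3 at 2.95 ± 0.156. Cytokines and chemokines of epithelial inflammation rose in 23 of 27 (23 adjusted over the list alone). The largest falls were in AFAP1L2 (-1.42 ± 0.106) and KCNJ8 (-1.40 ± 0.127). Limma called 2792 probes (1309 rose, 1483 fell). Rises outnumbered falls on leaving out P replicate 1 (1064 and 954), 2 (1117 and 1107) or 3 (1117 and 1019), or P+C replicate 3, where 1857 were called (964 and 893). Of the 56 probes called in C against Control, 35 rose in both comparisons, against 4.2 from independent lists. Falls did not overlap beyond that, with 2 in both against 2.25, and 6 probes had opposite signs. Both comparisons use the fit's shared estimate of spread for each probe, so their calls are not fully independent.

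The test of progesterone by infection asked whether the response to progesterone differed between infected and uninfected cells. Among genes detected in all of these groups, the difference was 4.19 ± 0.172 for S100A8, 3.92 ± 0.23 for TNF, 3.65 ± 0.193 for BIRC3 and 3.36 ± 0.286 for LCN2. CCL20, IL8, CXCL10 and IL17C also passed, but none was detected on all arrays of P, C and Control, so no size is given for them. Negative differences were largest for PSCA (-1.48 ± 0.232, detected on 2 of 3 P+C arrays) and for KITLG, the ligand of the KIT receptor (-1.30 ± 0.219). Cytokines and chemokines of epithelial inflammation differed upward in 22 of 27 (23 adjusted over the list alone), NF-kB regulators and feedback inhibitors in 14 of 23 (18 adjusted over the list alone), and MHC and antigen presentation in 8 of 16 (9 adjusted over the list alone). Interferon-stimulated genes did so in 11 of 38 (12 adjusted over the list alone), with adjusted p = 0.246 with an estimated correlation. In all, 1147 probes differed, 743 upward and 404 downward.

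Oestradiol without infection, E against Control, raised TFF1, a secreted trefoil peptide and classical oestrogen target, by 3.44 ± 0.118. The GDNF receptor GFRA1 rose at least 9.14-fold (3.26 ± 0.125), TFF3 by 3.23 ± 0.114, and the growth regulator GREB1 at least 4.65-fold (2.69 ± 0.148). PGR rose at least 1.36-fold (1.11 ± 0.0862). Falls were largest in NXPH1, a secreted neurexin ligand (at least 6.59-fold, -2.77 ± 0.113), the conjugating enzyme UGT1A6 (-2.14 ± 0.312, and -0.91 without E replicates 1 and 3), TMEM140 (-1.98 ± 0.133) and CTGF (-1.88 ± 0.0877). Both hormones together, E+P against Control, raised TFF1 by 3.25 ± 0.118, GFRA1 at least 8.44-fold (3.15 ± 0.125) and GREB1 at least 5.79-fold, and lowered NXPH1 by -2.69 ± 0.113 and UPK1A, a urothelial membrane protein, at least 3.94-fold (-2.08 ± 0.148).

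Oestrogen-responsive genes rose in 32 of 37 with oestradiol and 1 fell (32 and 1 adjusted over the list alone, median 1.05, adjusted p = 2.01e-26), and gave the same counts with both hormones. S and G2/M phase genes rose in 25 of 39 with oestradiol (31 adjusted over the list alone), among them the spindle factor TPX2 (1.04 ± 0.153) and the mitotic kinase AURKA (0.84 ± 0.122), which stood at 0.56 and 0.40 without E replicates 1 and 3. Replication-dependent histones fell in 14 of 16 (14 adjusted over the list alone), with HIST1H4H at -1.74 ± 0.14, and steroid and xenobiotic metabolism fell in 12 of 20 (12 adjusted over the list alone), with CYP1A1 at least 2.04-fold lower (-1.33 ± 0.139). Interferon-stimulated genes gave 1 rise and 15 falls among 38 (2 and 15 adjusted over the list alone), with adjusted p = 0.523 with an estimated correlation, and the list was not called without E replicate 3. Epithelial cell and junction markers gave 1 rise and 12 falls among 26 (1 and 14 adjusted over the list alone, median -0.34, adjusted p = 0.0066), with the surface glycoprotein CD24 at -1.19 ± 0.152 and the tight junction proteins CLDN1 and CGN at -1.10 ± 0.153 and -1.06 ± 0.104. Without E replicates 1 and 3 that list was not called and CD24 stood at -0.73. Stromal and mesenchymal markers gave 1 rise and 4 falls among 6 (1 and 4 adjusted over the list alone), with S100A4 at -1.51 ± 0.178 (-0.84 without E replicates 1 and 3), and progesterone- and glucocorticoid-responsive genes gave 5 rises and 15 falls among 29 (5 and 15 adjusted over the list alone). Each of these had adjusted p = 0.173 with an estimated correlation. Neither was called among probes detected on every array, and the first was not called with no filter on dim probes. The second was not called without Control replicate 1, without E replicate 3, or without E replicates 1 and 3 together.

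With both hormones, S and G2/M phase genes rose in 24 of 39 (32 adjusted over the list alone), replication-dependent histones fell in 13 of 16 (13 adjusted over the list alone) and steroid and xenobiotic metabolism fell in 10 of 20 (10 adjusted over the list alone). Epithelial cell and junction markers fell in 7 of 26 (7 adjusted over the list alone), CD24 by -0.76 ± 0.152 and CGN by -0.72 ± 0.104, with adjusted p = 0.0852 with an estimated correlation. Interferon-stimulated genes gave 1 rise and 12 falls among 38 (1 and 13 adjusted over the list alone), with adjusted p = 0.403 with an estimated correlation. Limma called 4105 probes with oestradiol (1960 rose, 2145 fell) and 2999 with both hormones (1470 rose, 1529 fell). E replicates 1 and 3 stood apart from replicate 2, and without both the oestradiol count was 2531 (1272 rose, 1259 fell). Without E+P replicate 1, the count with both hormones was 1197 rises and 1189 falls.

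In infected cells, oestradiol (E+C against C) raised MGP, an inhibitor of matrix calcification, by 3.40 ± 0.228, TFF1 by 3.39 ± 0.118 and GREB1 at least 5.9-fold. Both hormones (E+P+C against C) raised TFF1 by 3.52 ± 0.118 and MGP by 3.32 ± 0.228. NXPH1 fell by -2.57 ± 0.113 and -2.68 ± 0.113. IL6 and IL8 lay below background in C, E+C and E+P+C. Oestrogen-responsive genes rose in 33 of 37 and 32 of 37 and 1 fell in each comparison (34 and 33 rose, and 1 and 2 fell, adjusted over the list alone). S and G2/M phase genes rose in 21 and 19 of 39 (24 and 25 adjusted over the list alone), with MCM7 at 1.03 ± 0.115 in E+C. Interferon-stimulated genes fell in 33 of 38 in each comparison, OAS1 by -1.41 ± 0.206, OAS2 by -1.36 ± 0.293 and XAF1 by -1.35 ± 0.202 with oestradiol. That count was also 33 adjusted over the list alone in each, with adjusted p = 0.104 and adjusted p = 0.0812 with an estimated correlation. MHC and antigen presentation fell in 9 of 16 in each (10 and 11 adjusted over the list alone).

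Epithelial cell and junction markers gave 1 rise and 12 falls among 26 in E+C (1 and 12 adjusted over the list alone), and 1 rise and 9 falls in E+P+C (1 and 9 adjusted over the list alone), with CD24 at -0.84 ± 0.152 and -0.60 ± 0.152. In E+P+C the list had adjusted p = 0.0531 with an estimated correlation and was not called without C replicate 1. Replication-dependent histones gave 1 rise and 12 falls among 16 in each (1 and 13 adjusted over the list alone in each), with HIST1H4H at -1.03 ± 0.14 and -0.97 ± 0.14, and steroid and xenobiotic metabolism fell in 10 of 20 in each (10 adjusted over the list alone). Unfolded protein and integrated stress response genes gave 8 rises and 3 falls among 30 in E+C (11 and 4 adjusted over the list alone), and 11 rises and 4 falls in E+P+C (11 and 5 adjusted over the list alone), with adjusted p = 0.196 and adjusted p = 0.176 with an estimated correlation. Neither call was made without C replicate 3, nor without E+C replicate 2 or E+P+C replicate 2 in turn. Ribosomal proteins gave 9 rises and 1 fall among 36 in E+P+C (9 and 1 adjusted over the list alone), with adjusted p = 0.122 with an estimated correlation, and were not called without C replicate 1 or 2 or E+P+C replicate 2 or 3, with neqc or without background correction.

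Limma called 3522 probes in E+C against C (1820 rose, 1702 fell) and 3187 in E+P+C against C (1640 rose, 1547 fell). Comparisons with no array in common gave overlapping calls, although they share the fit's estimate of spread for each probe and so are not fully independent. Of probes called in E+C against C and in E against Control, 1023 rose and 1029 fell in both, against 301 and 308 from independent lists, and changes correlated at 0.646 across probes, which are not independent replicates.

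**Figure D3:**
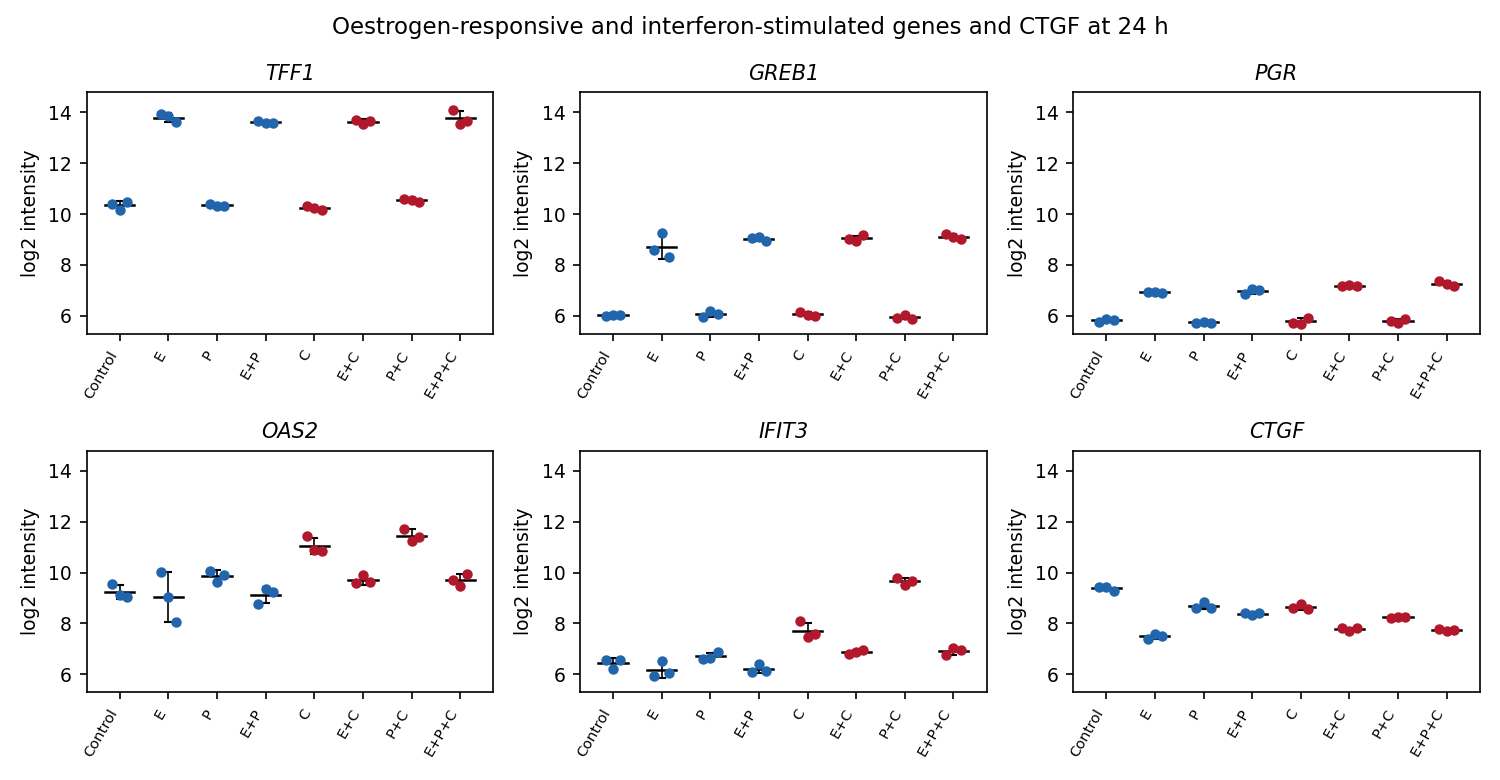
Log2 intensity at 24 h of 3 oestrogen-responsive genes, 2 interferon-stimulated genes and CTGF, with uninfected groups in blue, infected groups in red, a point per array, a bar at the mean and an error bar of 1 SD. TFF1 averaged 13.8 in E and 10.35 in Control, and OAS2 averaged 11.05 in C and 9.23 in Control.

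The steroids were set against each other at doses the labels do not state, so the contrast is of the treatments as given. In infected cells, P+C against E+C, CCL20 was at least 85.4-fold higher (6.49 ± 0.135), IL8 by 6.03 ± 0.0999 (at least 44-fold) and CYP3A5, a drug-metabolising enzyme, at least 6.12-fold (3.00 ± 0.106), while TFF1 was lower by -3.09 ± 0.118 and MGP by -3.19 ± 0.228. All 38 measured interferon-stimulated genes were higher (38 adjusted over the list alone, median 1.30, adjusted p = 0.0065 with an estimated correlation), and 35 of 39 S and G2/M phase genes were lower (37 adjusted over the list alone, median -0.66). Limma called 4173 probes (1777 higher, 2396 lower). In uninfected cells, P against E, NXPH1 was at least 6.23-fold higher (2.69 ± 0.113) and TFF1 lower by -3.45 ± 0.118, and IL6 and IL8 lay below background in both groups. There 24 of 38 interferon-stimulated genes were higher (24 higher and 1 lower adjusted over the list alone), with adjusted p = 0.228 with an estimated correlation. Limma called 4297 probes (2198 higher, 2099 lower), and 2177 without E replicates 1 and 3 (1040 higher, 1137 lower). Without E replicate 1 they were 1602 higher and 1631 lower.

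Infection in the presence of oestradiol, E+C against E, raised SRP9, a signal recognition particle subunit, by 1.53 ± 0.3 and AGR3 by 1.34 ± 0.245, and lowered ZNF91, a zinc finger repressor, by -1.51 ± 0.244 and CARM1, an arginine methyltransferase, by -1.45 ± 0.25. Without E replicates 1 and 3 these changes were 0.37, 0.29, -0.95 and -0.76, and none was called. Interferon-stimulated genes rose in 17 of 38 (18 adjusted over the list alone), with adjusted p = 0.668 with an estimated correlation. Limma called 2291 probes (1152 rose, 1139 fell). The count was 558 without E replicate 1 (273 rose, 285 fell), 888 without E replicate 3 (423 rose, 465 fell), 4410 without E replicate 2, 1147, 1378 and 973 without E+C replicate 1, 2 or 3, and 0 without both E replicates 1 and 3.

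Infection in the presence of both hormones, E+P+C against E+P, lowered CTGF by -0.65 ± 0.0877 (adjusted p = 0.00169, limma). It was the 1 probe called, with 834 at an unadjusted p under 0.05. FOS at -0.79 ± 0.145 and EGR1 at -0.57 ± 0.117 did not pass. None of 38 interferon-stimulated genes passed over all probes and 9 rose adjusted over the list alone, with a median of 0.31, XAF1 at 0.87 ± 0.202 and IFIT3 at 0.71 ± 0.156. The list was called at adjusted p = 5.01e-20, but had adjusted p = 0.217 with an estimated correlation. The other list called was cytokines and chemokines of epithelial inflammation, with no member passing over all probes. It lost its call with an estimated correlation and among probes detected on every array. The same held without E+P replicate 2 or 3, or E+P+C replicate 1 or 2. Whether infection acted differently in any hormone state was tested with limma's F test of the interaction terms, which called 1580 probes. That count was 948 without P+C replicate 3, 1028 without P+C replicate 1 and 4280 without E replicate 2.

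**Figure D4:**
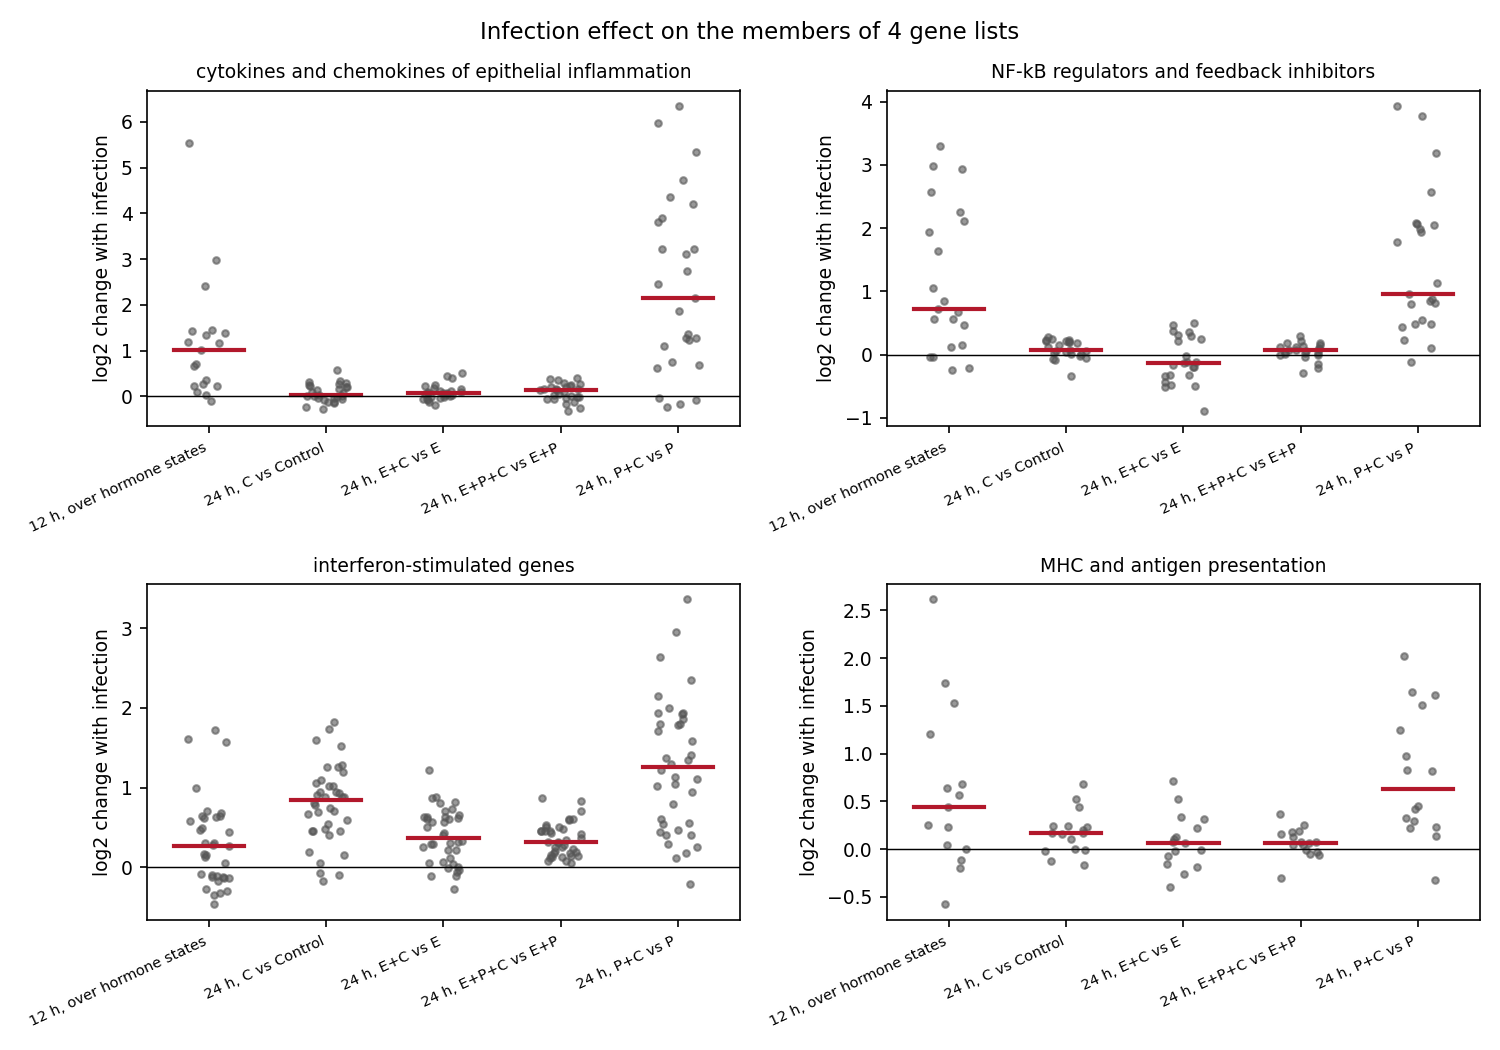
Log2 change with infection (vertical axis) of each measured member of 4 gene lists, at 12 h over the hormone states and at 24 h in each hormone state, with a point per gene and a red line at the median. For cytokines and chemokines of epithelial inflammation the median was 1.01 at 12 h (19 measured genes) and 2.15 for P+C against P at 24 h (27 measured genes). The sets of measured genes thus differ between the times.

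At 12 h, infection was tested over the 4 hormone states (4 infected arrays against 4 uninfected). IL6 rose at least 38.8-fold (5.53 ± 0.161) and IL8 at least 5.01-fold (2.97 ± 0.117). CYP1A1 and CYP1B1, enzymes induced through the aryl hydrocarbon receptor, rose by 4.27 ± 0.156 and 3.05 ± 0.117, BIRC3 at least 8.52-fold (3.30 ± 0.141) and the NF-kB subunit gene NFKB2 by 2.93 ± 0.147. Falls were largest in SERPINB5, a serpin of epithelia (-2.02 ± 0.135), DDIT4, an inhibitor of mTOR (-1.86 ± 0.12), INSIG1, a regulator of cholesterol synthesis (-1.81 ± 0.114), and the chaperone HSPA1B (-1.78 ± 0.148).

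Immediate early genes gave 21 rises and 2 falls among 28 (22 and 2 adjusted over the list alone), with KLF10 at 2.73 ± 0.177 and FOSB at 1.71 ± 0.149. Cytokines and chemokines of epithelial inflammation rose in 13 of 19 (13 adjusted over the list alone), with the adhesion molecule ICAM1 up at least 3.76-fold (2.41 ± 0.138), and NF-kB regulators and feedback inhibitors in 15 of 21 (15 adjusted over the list alone), with TNFAIP3 at 2.98 ± 0.138 and RELB at 2.57 ± 0.126. These 3 lists each had adjusted p = 0.021 with an estimated correlation. The other 11 of 14 called lists lost their call that way. Among them, MHC and antigen presentation gave 8 rises and 1 fall among 15 (8 and 1 adjusted over the list alone), led by TAP1 at 2.62 ± 0.117, with adjusted p = 0.0929 with an estimated correlation. Cholesterol synthesis and uptake gave 1 rise and 14 falls among 27 (1 and 18 adjusted over the list alone), with SQLE, an enzyme of that pathway, at -0.93 ± 0.145, and adjusted p = 0.104 with an estimated correlation. Heat shock response gave 1 rise and 8 falls among 19 (1 and 8 adjusted over the list alone), with HSPA8 at -1.64 ± 0.135, and adjusted p = 0.0929 with an estimated correlation. Interferon-stimulated genes gave 13 rises and 1 fall among 35 (13 and 1 adjusted over the list alone), with adjusted p = 0.302 with an estimated correlation. Limma called 3466 of 11336 probes (1617 rose, 1849 fell), and 2072 without the E array of 12 h.

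**Figure D5:**
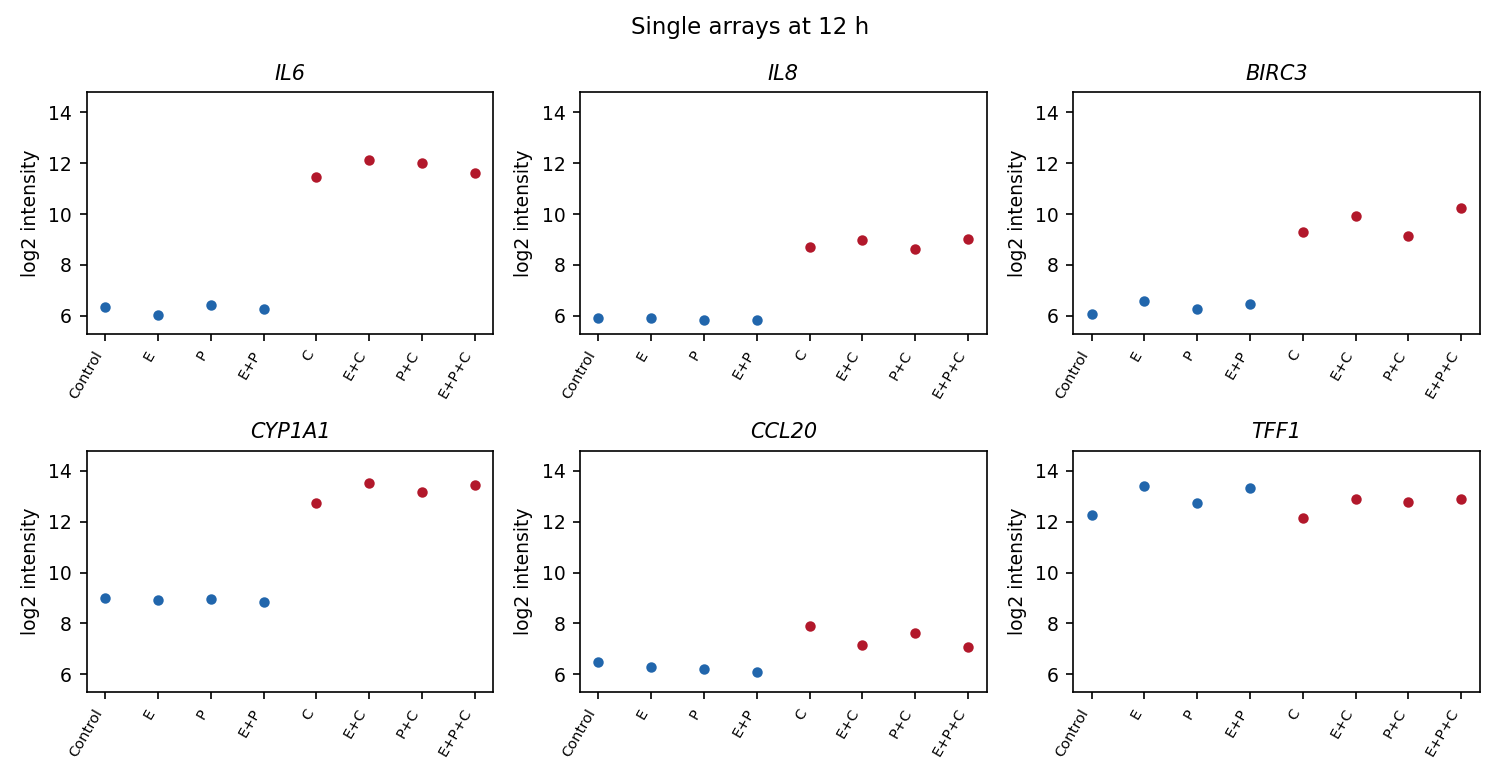
Log2 intensity of 6 genes on the 8 single arrays of 12 h, uninfected in blue and infected in red, with no replicate and so no error bar. Infected arrays averaged 11.79 for IL6 and 13.21 for CYP1A1, and uninfected arrays 6.26 and 8.94.

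Each 12 h group is a single array, so the following differences have no replicate check. IL6 was below background on each uninfected array and stood at 11.47 in C, 11.99 in P+C, 12.11 in E+C and 11.60 in E+P+C. IL8, also below background without infection, stood at 8.71, 8.63, 8.99 and 9.03. The medians of cytokines and chemokines of epithelial inflammation were 0.86, 0.94, 0.85 and 0.88, each at percentile 100 of random lists. P+C minus C at 12 h was 0.52 for IL6 and -0.08 for IL8.

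Progesterone over the other factors at 12 h gave 0 calls with limma, with 59 probes at an unadjusted p under 0.05, and the smallest p belonged to SEMA5B (-0.41 ± 0.129). Camera called 5 lists there, with medians from -0.08 to 0.10 and no member passing, and each lost its call at adjusted p = 0.46 or above with an estimated correlation. Oestradiol gave 0 calls, with 2848 probes at an unadjusted p under 0.05, and 1926 calls when its term came from a joint fit of all 32 arrays. SCIN, an actin-severing protein, stood at 0.77 ± 0.127 and KRT81, a hair keratin, at -0.77 ± 0.138, both at adjusted p = 0.117 (limma). Of 31 oestrogen-responsive genes at 12 h, none passed over all probes and 9 rose adjusted over the list alone (median 0.27), with adjusted p = 0.621 with an estimated correlation. GREB1 and PGR were below background on the 12 h arrays.

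The infection effect, averaged over hormone states, was compared between 24 h and 12 h. It was smaller at 24 h for CYP1B1 (-3.03 ± 0.12) and TIPARP, a further aryl hydrocarbon receptor target (-2.54 ± 0.126), and for IL6 and CYP1A1, which were below background in some groups and so are given no size. It was more positive at 24 h for INSIG1 (2.10 ± 0.241), DDIT4 (2.05 ± 0.133) and HSPA1B (1.91 ± 0.189), which were among the largest falls with infection at 12 h. Immediate early genes differed downward in 21 of 29 and upward in 2 (23 and 2 adjusted over the list alone), and cholesterol synthesis and uptake upward in 15 of 29 and downward in 1 (15 and 2 adjusted over the list alone). Interferon-stimulated genes differed upward in 22 of 38 and downward in 4 (24 and 4 adjusted over the list alone), IFIT1 by 1.51 ± 0.308 and IFIT2 by 1.15 ± 0.18, with adjusted p = 0.322 with an estimated correlation. Limma called 4134 of 12789 probes (2205 upward, 1929 downward). The 24 h average joins unlike hormone states, as infection called 2792 probes with progesterone, 2291 with oestradiol, 56 without hormone and 1 with both. No label gives a batch, and time and array batch cannot be told apart here.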

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

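Tests chosen only after the result was seen were those for immune cells, for 12 h samples in place of P+C samples, for a response still running, for a different cell population, for the sizes of the E+C against E changes, and the fits without E or P replicates 1 and 3.

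The response to progesterone differed between infected and uninfected cells in 1147 probes by the interaction test. Among 100 splits of the arrays, 6 gave as many, the real one included, with 1232 as the highest of the others, so this count does not exclude chance. The 5 others all kept the P+C arrays apart from the C arrays, as 13 of the other splits did, and the highest count among splits that did not was 1. The F test of hormone by infection called 1580 probes, and 1 of 100 splits, the real one, gave as many (highest other 619). The other splits all mixed infected groups, so hormone effects entered their residual spread. That share therefore does not exclude chance. The infection effect differed between 24 h and 12 h in 4134 probes, and 2 of 100 splits gave as many (highest other 4576), a share under 0.05. Splits that mix infected with uninfected arrays leave infection effects in their residual spread, so this share does not exclude chance either.

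Inflammatory genes stood high at 24 h in P+C and not in C, E+C or E+P+C. Immune cells mixed into the P+C cultures were argued against: transcripts abundant in leukocytes (PTPRC, LYZ, LAPTM5 and TYROBP) were detected on 0 P+C arrays, although ITGAM stood at 1.06 and CD68 at 0.45 among the 5 markers detected on all of them, and the median P+C minus C difference over 22 markers (0.0145, quartiles -0.0441 and 0.0608) mostly describes background, as 15 were detected on none. Infected 12 h samples in place of the P+C samples stay open, since time and array batch cannot be told apart: over the 301 probes that rose by at least 1 log2 unit in P+C against C, infection at 12 h gave a median of 0.398 (quartiles 0.0428 and 0.991), short of the 1.62 of P+C minus P by a median of 1.18 (lower quartile 0.699), but uninfected 12 h and 24 h arrays differed at these probes by up to 0.926 at the upper quartile. Of the 301 probes, all detected on every P+C array, 44 were detected on no infected 12 h array. The P+C arrays correlated at 0.914 or more with the other 24 h groups and at 0.879 or less with the 12 h arrays. That argues against 12 h arrays filed as P+C, but not against RNA of 12 h samples hybridised with the 24 h arrays. A candidate explanation that also stays open is that the response of 12 h was still running in P+C: over 217 of the 225 probes that rose by at least 1 log2 unit at 12 h, the median P+C minus P difference was 0.462 (quartiles 0.0332 and 1.49), with 120 rises and 12 falls, against medians of 0.0548 in C, 0.1 in E+C and 0.0461 in E+P+C against their uninfected groups. Progesterone without infection called 1 probe and gave a median of -0.0139 over those 301, which leaves open an effect of progesterone that needs infection, and a difference between the cultures in infection load or timing was not tested.

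The 12 h arrays differed from the 24 h arrays in every group. Differences at the level of probes, such as hybridisation or RNA fragmentation, may contribute: the 12 h minus 24 h difference correlated at 0.258 over 376 pairs of probes of the same gene, against 0.716 over 55 pairs for E minus Control and 0.758 over 47 for infection at 12 h. A low value is not peculiar to time, since P+C minus C gave 0.398 over 32 pairs and E+C minus E, which includes E replicates 1 and 3, 0.019 over 37. Higher values came from E+P minus Control (0.812 over 22), E+C minus C (0.632 over 33) and E+P+C minus C (0.656 over 30). Pairs are not independent replicates. A different cell population at the 2 time points stays open, with 53 genes on at one time and off at the other (4 at 12 h, 49 at 24 h), against 5 between arrays with and without oestradiol. Time and array batch cannot be told apart, and a biological change with time stays open, untested.

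E replicates 1 and 3 stood apart from E replicate 2 at 24 h. Without both, the E+C against E comparison called 0 probes in place of 2291 (limma, 3987 at an unadjusted p under 0.05 with all arrays), while P+C against P without P replicates 1 and 3 called 1190, of which 1165 were among its 2792, so how many calls rest on those arrays stays open, because a lone array lowers the power. The sizes, which power does not change, rest largely on E replicates 1 and 3: over the 2291 probes, the median share of the change left with E replicate 2 alone was 0.393 (quartiles 0.163 and 0.657), with 258 turning sign, against 0.994 to 1.01 with a lone P array for P+C against P. Probe-level differences may be the source: E replicate 1 minus replicate 2 correlated at 0.0356 over 217 pairs of probes of the same gene. No biological explanation was tested, since the arrays are replicates.

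The comparisons of 3 arrays against 3 have 10 splits, too few for a share under 0.05, and in each of the following 1 split, the real one, gave as many probes. The real count and the highest other were 2343 and 0 for P+C against C, 3522 and 6 for E+C against C, 3187 and 0 for E+P+C against C, 1 and 0 for P against Control, and 4105 and 671 for E against Control. They were 2999 and 0 for E+P against Control, 56 and 3 for C against Control, 2792 and 0 for P+C against P, 2291 and 1101 for E+C against E, and 1 and 0 for E+P+C against E+P. For P+C against E+C they were 4173 and 0, and for P against E 4297 and 1071. Infection at 12 h called 3466 probes, and 1 of 33 splits, the real one, gave as many (highest other 0). The other splits leave some of the infection effect in their residual spread, and each treatment has 1 array. That share therefore cannot exclude chance. Progesterone at 12 h (0 calls with limma, 59 at an unadjusted p under 0.05) has a count that every split matches (33 of 33), so the share decides nothing, and the highest of the others called 618, a division of the arrays that was not examined further. Oestradiol at 12 h (0 calls with limma, 2848 at an unadjusted p under 0.05) was likewise matched by 33 of 33, with 0 as the highest other.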

How the results depend on the processing

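Chosen after the data were seen were normexp as the main correction and neqc, named in the design, as an alternative to it. So were the fits without E or P replicates 1 and 3, and leaving out each array for the time difference. None of 150 list calls became a call in the other direction, and none of 737 named gene values changed sign. A list that turned without being called was counted as lost. Of 18 counts, 6 changed which was larger, rises or falls, in at least 1 setting. This was so for P+C against C in 6 of 13 settings (826 rose and 1017 fell among probes detected on every array), P+C against P in 5 of 14 (749 rose and 441 fell without P replicates 1 and 3), E+C against E in 4 of 14, P against E in 2 of 14, and E and E+P against Control in 1 of 14 and 1 of 13. All 18 counts stayed within 1.5 times without background correction, with median scaling, with the deposited value table and with neqc, and so did the 14 counts fitted with a replicate block (2234 for P+C against C, in place of 2343). Median scaling could change little, since array medians were already nearly equal. The value table, its rows paired with the scanner rows by closest values, nearly repeats the setting without background correction. Neither is a separate check, and the exchanged probe identifiers were not tested. List calls were lost in 54 of 150 cases with an estimated correlation, in 87 on leaving out 1 array (905 were kept), in 22 when probes had to be detected on every array and in 11 with no filter on dim probes. Among named genes, 126 of the calls compared were lost on leaving out 1 array, 33 without E replicates 1 and 3, and 3 with a replicate block. A block by chip was not run, since no chip is named. Dim genes near background are limited by the offset and by detection.

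P against Control called 2 probes with no filter on dim probes and 3 among probes detected on every array, in place of 1. Oestradiol at 12 h called 1926 in the fit of all 32 arrays, in place of 0 (2848 at an unadjusted p under 0.05, limma). Without E replicates 1 and 3 the counts were 2531 for E against Control, 0 for E+C against E (limma) and 2177 for P against E, and P+C against P called 1190 without P replicates 1 and 3. These fits leave 1 array, assumed to vary like the other groups. Leaving out 1 array at a time, counts ranged from 558 to 4410 for E+C against E, from 948 to 4280 for the F test, from 1857 to 2224 for P+C against P, from 1511 to 2342 for P+C against C, from 765 to 1222 for progesterone by infection, and from 2072 to 3896 for infection at 12 h. C replicate 3 stood apart, and without it the counts were 2305 for P+C against C, 3164 for E+C against C, 2985 for E+P+C against C and 71 for C against Control. Fewer arrays lower the power. The difference of C replicate 3 from C replicates 1 and 2 correlated at 0.234 over 39 pairs of probes of the same gene. Probe-level differences may thus contribute there, and other causes were not tested.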

Other observations

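The contrasts of progesterone in the presence of oestradiol and the tests on oestradiol and on the aryl hydrocarbon receptor were chosen after the data were seen.

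Progesterone was also compared in cells that had oestradiol. In uninfected cells, E+P against E, limma called 430 probes (228 rose, 202 fell), and E replicates 1 and 3 stand apart in that comparison. CTGF rose there by 0.89 ± 0.0877 (adjusted p = 6.17e-06, limma), opposite in sign to its -0.68 ± 0.0877 in P against Control, and stood at -1.88 in E against Control. In infected cells, E+P+C against E+C, limma called 0 probes, with 536 at an unadjusted p under 0.05, and S100A8 differed by -0.18 ± 0.122. The difference between P+C against C and E+P+C against E+C passed for 1140 probes (730 upward, 410 downward), with S100A8 at 4.26 ± 0.172 and TNF at 4.02 ± 0.23.

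The P+C response was not seen in E+P+C, and oestradiol may act against it. Over the 301 probes that rose by at least 1 log2 unit in P+C against C (median 1.52), the median E+P+C minus E+C difference was 0.000245 (quartiles -0.0731 and 0.076), with 0 rises and 0 falls by limma (536 of all probes at an unadjusted p under 0.05). The P+C arrays differ from all other groups, so a property of those cultures other than progesterone would give the same values.

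CYP1A1, CYP1B1 and TIPARP, which respond to the aryl hydrocarbon receptor, rose with infection at 12 h. Activity of that receptor is a candidate explanation that stays open: of 5 further target genes measured (10 were listed), 1 rose, NFE2L2 at 1.18 ± 0.14, UGT1A6 fell by 0.33, and AHRR (0.26 ± 0.148), NQO1 (0.14 ± 0.13) and ALDH3A1 (0.04 ± 0.127) did not pass.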
